A study of Rattus norvegicus with 154 samples.

How the data were processed

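Lung RNA of 77 rats was hybridised to Affymetrix RAE230A arrays, per the file headers, with 2 chips, A and B, per animal. The deposited table held linear intensity values for 15923 probe sets, and the program used for summarisation was not given in the sources used here. The deposited values had a 2% trimmed mean of 150 on every array, as seen from the values themselves. Array medians lay between 67.7 and 100.1, a ratio of 1.48, and the scaling of the authors was kept. All columns were assigned to a group and no arrays had identical values. Pearson correlations were taken on log2 values with the offset, over the 11106 probe sets kept by the filter described below. The 2 chips of an animal had a median correlation of 0.978 (77 pairs, 0.923 to 0.99), against 0.953 for chips of other animals of the same group and 0.937 for animals of other groups.

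The 57 control probe sets were left out of the tests, an offset of 7 (the 10th percentile of all values) was added, and log2 was taken. The mean of chips A and B was used as the value of an animal, so that animals were the replicates. Probe sets in the lowest 30% of mean values were left out, which left 11106. Differences of low-intensity probe sets near the offset are understated by the offset. Genes came from the probe table, in which 12783 probe sets had 1 gene, 312 had several and 2771 had none. Symbols of 12748 were matched by gene ID to the RefSeq gene table of assembly GRCr8, which was used for names only.

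A linear model with a mean for each of the 25 groups was fitted in R 4.3.3 with limma 3.58.1 (statmod 1.5.0), with moderated t tests, two-sided p values and Benjamini-Hochberg adjustment over all tested probe sets per comparison, at a threshold of 0.05. The comparisons were each dose against isopropyl alcohol at the same time, isopropyl alcohol against saline, a linear trend over dose, 6 against 3 mg at 24 h, and an F-test of whether the 6 mg effect differed between times. The doses share the isopropyl alcohol animals of their time. In all, 25 gene lists were fixed before the data were examined and tested with camera in each of 20 comparisons, with a preset correlation of 0.01 and again with a correlation estimated per list, and p values were adjusted over the 25 lists. Members were counted as higher or lower with the adjustment over all probe sets and, where stated, adjusted over the list alone. With the preset correlation, other divisions of the animals gave a median of 72 list calls against the real 78. An adjusted p with that correlation alone thus does not tell a list shift from chance.

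The genes named were set by a rule written with the comparisons. A gene was represented by its probe set with the highest mean, among probe sets with 1 gene. For 6 mg the 12 largest rises and 12 largest falls were named, and for other comparisons 5 and 5, among genes with an adjusted p under 0.05 whose treated and control animals did not overlap, a pattern that chance gives in 10% of splits of 3 against 3 animals. Up to 4 passing members of a list were named, by smallest adjusted p, or up to 2 where none passed, and 10 genes for the difference between times. SE is that of the model, SD is that of the animals' intensities.

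Scan days were read from the array files and numbered in order. There were 17 scan days in 12 pairs of chip A and chip B days, and 7 arrays carried a note on a regenerated probe. Alternatives were another offset, filter, floor or normalization, each chip alone, all arrays in the fit, array weights, scan days as a block, only the groups of a time, and each animal left out. Alternatives chosen after seeing the data were 3'/5' ratios as covariates and the fit without the 3 animals of the 13th and 14th scan days. These 3 had chip A scanned on the 13th and chip B on the 14th day. The 6 mg replicate 1 at 1 h, with only chip B scanned on the 14th day, was kept. That animal and 6 mg replicate 4 at 30 min were each alone on their pair of scan days. Neither therefore counted in the fit with scan days as a block. RNA integrity was measured as the log2 ratio of 3' to 5' control probe sets for GAPDH and beta-actin, and compared with exact permutation tests per time. Simulated data had 100 changed probe sets per size among 11106, with independent normal noise and no effect of scan day. There the test of 6 mg against isopropyl alcohol at 30 min recovered 91% of changes of log2 1 and 46% of log2 0.5, with 10 false among 147 calls. That at 24 h recovered 85% and 27%, with 4 false among 116. These rates do not cover scan-day effects or noise shared between genes in the real data. Histology, protein levels and injury scores were not analysed here.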

Results

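Messenger RNA levels were measured in lungs of rats exposed to sulfur mustard, an alkylating agent that forms adducts and crosslinks in DNA. The animals had received 1, 3 or 6 mg of the agent in isopropyl alcohol, isopropyl alcohol alone (0 mg) or saline, and lungs were taken after 30 min or after 1, 3, 6 or 24 h. The labels gave the doses in mg without a body weight. There were 77 animals with 2 chips each, in 25 groups. Of the groups 23 had 3 animals and 2 had 4, which were 6 mg at 30 min and 6 mg at 1 h. The median intensity per array lay between 67.7 and 100.1. In all, 11106 probe sets were tested, which named 8042 genes.

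The first question was what 6 mg did to lung gene expression over time, against isopropyl alcohol alone. Numbers of changed probe sets were 0 at 30 min, 21 at 1 h, 1437 at 3 h, 2025 at 6 h and 747 at 24 h (limma, adjusted p under 0.05). At 3 h 426 were higher and 1011 lower, at 6 h 796 were higher and 1229 lower, and at 24 h 301 were higher and 446 lower.

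**Figure D1:**
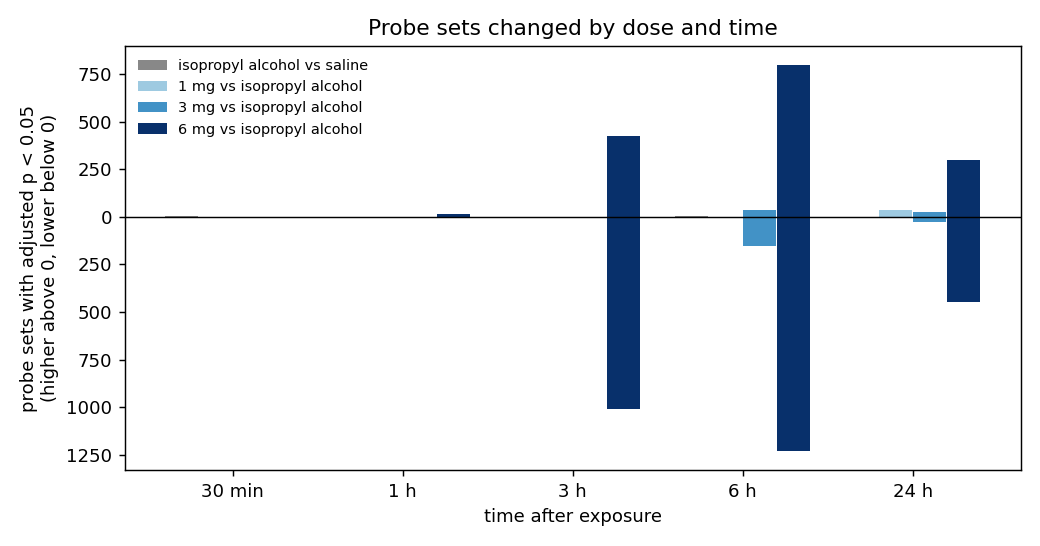
Numbers of probe sets with adjusted p under 0.05 (y axis, higher above 0 and lower below 0) for each dose against isopropyl alcohol, and for isopropyl alcohol against saline, at each time after exposure (x axis). Bars are counts from limma, and at 6 mg they reach 796 higher and 1229 lower at 6 h.

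At 30 min no gene passed the test in the 6 mg animals (n = 4) against isopropyl alcohol (n = 3). Ddit4, a stress-induced inhibitor of mTOR signalling, had a log2 fold change of 1.33 ± 0.35 (SE) with an adjusted p of 0.573. Sgk1, a kinase induced by glucocorticoids, stood at 0.45 ± 0.13 with an adjusted p of 0.598. The glucocorticoid-responsive list, with 0 of 18 measured members past the test and 2 higher when adjusted over the list alone, had a median of 0.21 (camera, adjusted p = 0.000243, and adjusted p = 0.364 with an estimated correlation). The cardiac and muscle list had a median of -0.32 over 15 members, 0 of which passed (adjusted p = 0.000152, and adjusted p = 0.596 with an estimated correlation). The limma count of 0 became 27 with array weights and 1 without 6 mg replicate 1. It stood beside 583 probe sets with an unadjusted p under 0.05. Chance alone gives such a p to a share of about 0.05 of the 11106 tested, here and below. The 583 are near that share. The cardiac and muscle median was -0.05 without isopropyl alcohol replicate 3. The pairs of scan days that held both groups had 2 against 2 and 1 against 1 animal. In them the glucocorticoid-responsive median was 0.09 and 0.64, and the cardiac and muscle median was -0.04 and -0.88.

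At 1 h the 6 mg animals (n = 4) had higher levels of immediate early genes than the animals given isopropyl alcohol (n = 3), with 13 probe sets higher and 8 lower. Atf3, a transcription factor induced by cellular stress, rose 3.88-fold, from an intensity of 46.1 ± 3.29 to 210.3 ± 82.6 (SD), with a log2 fold change of 1.96 ± 0.44 (SE, adjusted p = 0.0438). Ier3, an immediate early gene, rose 2.70-fold (1.43 ± 0.26, adjusted p = 0.00591), and Nr4a1, an orphan nuclear receptor, rose 2.45-fold, from 209.3 ± 14.3 to 548.3 ± 167 (SD). Ppp1r15a, a regulatory subunit of the phosphatase that acts on eIF2-alpha, rose 1.97-fold (0.98 ± 0.20), and Csrnp1, Plk2, Brd2, Ppp1r18, Klf16 and Nubp2 rose between 1.41-fold and 1.75-fold. Prr5l (-0.67 ± 0.16) and Mpdz (-0.56 ± 0.12) were the genes with a name among the 8 lower probe sets.

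Of the 19 measured immediate early genes, 3 rose at 1 h, and 11 rose when adjusted over the list alone. The list had a median log2 fold change of 0.54 (camera, adjusted p = 2.25e-12, and adjusted p = 0.0156 with an estimated correlation). The inflammatory cytokine, chemokine and adhesion list had a median of 0.32 with 0 of 17 members past the test (list adjusted p = 0.036, and adjusted p = 0.419 with an estimated correlation). Its member Il1b, a cytokine gene, stood at 1.09 ± 0.41 with an adjusted p of 0.261. No pair of scan days held both groups at 1 h. With scan days as a block the count of 21 became 0, with Atf3 at 2.08 and an adjusted p of 0.24. In that fit 6 mg replicate 1, alone on its pair of scan days, did not count, so the estimate rests on the other 6 mg animals. With the block and the preset correlation the immediate early list kept a median of 0.54 (camera, adjusted p = 3.98e-07). The inflammatory list then had a median of 0.16 and its call was lost (adjusted p = 0.307). An estimated correlation was not used with the block for these lists, so whether the immediate early call would hold with it is open. Leaving out an animal gave 3, 6 or 8 probe sets without isopropyl alcohol replicate 1, 2 or 3 and 12, 5, 5 or 13 without 6 mg replicate 1, 2, 3 or 4, and each of the 12 named genes lost its call in 1 or more of these fits. The GAPDH 3'/5' log2 ratio, a sign of RNA integrity, was 1.36 ± 0.85 (SD) at 6 mg and 0.65 ± 0.43 in isopropyl alcohol.

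At 3 h heat shock and immediate early genes rose in the 6 mg animals against isopropyl alcohol (n = 3 each). Atf3 rose 10.4-fold, from 44.1 ± 3.31 to 554.1 ± 226 (SD), with a log2 fold change of 3.38 ± 0.47 (SE, adjusted p = 8.18e-07). The chaperone genes Dnajb1 (2.26 ± 0.36), Hspb1 (1.93 ± 0.30), Dnajb4 (1.52 ± 0.19) and Bag3, a co-chaperone (1.70 ± 0.28), rose between 2.87-fold and 4.78-fold, and their levels at 6 mg were spread widely between animals. Intensities at 6 mg and in isopropyl alcohol were 1791 ± 2440 (SD) and 170.2 ± 21.4 for Dnajb1, 4176 ± 3920 and 805.2 ± 190 for Hspb1, 832.5 ± 434 and 266.7 ± 66.9 for Dnajb4, and 1516 ± 1770 and 290.6 ± 13.2 for Bag3. Without 6 mg replicate 1 the log2 fold changes were 1.03, 1.18, 1.13 and 0.76, and all 4 still passed. Ppp1r15a rose 4.10-fold (2.04 ± 0.21, adjusted p = 1.01e-09), Ier3 rose 3.91-fold (1.97 ± 0.28), and Hmox1, which encodes haem oxygenase, rose 3.43-fold (1.78 ± 0.28, and 1.06 without 6 mg replicate 1). Adm, which encodes the vasodilator adrenomedullin, Slc25a25, Tubb6 and Plk2 rose between 2.94-fold and 3.34-fold, with Adm and Tubb6 at a log2 fold change of 1.11 and 0.93 without 6 mg replicate 3.

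Among the 1011 probe sets lower at 3 h, Bicra fell by 2.15 on the log2 scale (SE 0.43), to an intensity of 7.8 ± 2.2 (SD) that lay near the offset of 7. Tcf7l2, a transcription factor of the Wnt pathway, fell by 1.59 (SE 0.20, adjusted p = 1.37e-07), from 191.5 ± 16.5 to 68.1 ± 40.4. Rapgef2, Rapgef5 and Rapgef4, which encode exchange factors for Ras-like GTPases, fell 2.87-fold, 2.63-fold and 2.54-fold. Mertk, a receptor used in the uptake of dying cells, fell by 1.47 (SE 0.27), and Pard3, which encodes a cell polarity protein, fell by 1.32 (SE 0.24). Fam13c, Prickle2, Ankrd44, Meis2 and Prr5l fell between 2.47-fold and 3.13-fold, with Prickle2 at -0.87 and Meis2 at -0.81 without 6 mg replicate 3.

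Of 19 measured heat shock and unfolded protein response genes, 12 rose at 3 h (13 adjusted over the list alone), with a median of 0.86 (camera, adjusted p = 1.45e-12, and adjusted p = 0.00975 with an estimated correlation). Of 19 immediate early genes, 11 rose (13 adjusted over the list alone), Jun 2.46-fold and Ier5 2.22-fold among them, with a list median of 0.84 (adjusted p = 0.00975 with an estimated correlation). Jun went from a log2 fold change of 1.298 to 0.704 without 6 mg replicate 1. Of 16 p53 targets and DNA damage genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone), with Atf3, Plk2, Ddit3 (1.07 ± 0.20) and Ccng1 (0.81 ± 0.21) having the smallest adjusted p (list adjusted p = 0.016 with an estimated correlation). Atf3 and Ddit3 also stood on other lists. The oxidative stress and glutathione list had a median of 0.21 with 3 of 25 members higher (3 adjusted over the list alone), which were Hmox1, Srxn1 and Sod1 (adjusted p = 0.0199 with an estimated correlation). The hypoxia and glycolysis list had a median of 0.22 with 6 of 18 members higher (7 adjusted over the list alone), among them Hmox1, Adm, Tpi1 (0.70 ± 0.19) and Ldha (0.45 ± 0.13), and an adjusted p of 0.016 with an estimated correlation. Of 17 inflammatory genes, 5 rose (5 adjusted over the list alone), Cxcl2 by 1.48 ± 0.43 and Il1a by 1.05 ± 0.29 (other probe set 0.32) among them (list adjusted p = 0.0136, and adjusted p = 0.355 with an estimated correlation). Without 6 mg replicate 3 Ccng1, Cxcl2 and Ldha stood at 0.32, 0.51 and 0.30, and without isopropyl alcohol replicate 2 Tpi1 stood at 0.45.

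The 3 h count depended on 6 mg replicate 3, without which 285 probe sets changed. It was 836 without isopropyl alcohol replicate 2, 453 with only the groups of that time in the fit, 748 with array weights, 882 on chip B alone and 1482 with scan days as a block. With quantile normalization 382 probe sets were higher and 672 lower at 3 h. The array medians of 6 mg replicate 3, 67.7 and 68.5, were the lowest of all animals. The calls of Adm, Tubb6, Meis2, Ccng1, Il1a, Cxcl2, Sod1, Srxn1, Tpi1 and Ldha were lost in 1 or more of the fits without an animal. The heat shock median was 0.43 without 6 mg replicate 1, and the medians of p53 targets and immediate early genes were 0.25 and 0.53 without 6 mg replicate 3. The inflammatory median was 0.15 without isopropyl alcohol replicate 3, and that of hypoxia was 0.14 without isopropyl alcohol replicate 2. The 2 pairs of scan days that held both groups had 2 against 1 and 1 against 1 animal. In them the list medians were 1.04 and 0.19 for heat shock and 1.26 and 0.42 for immediate early genes. They were 0.25 and 0.28 for p53 targets, 0.20 and 0.09 for oxidative stress, 0.17 and 0.08 for hypoxia, and 0.79 and 0.12 for inflammatory genes. The GAPDH 3'/5' log2 ratio at 3 h was 1.05 ± 0.17 (SD) at 6 mg and 0.72 ± 0.22 in isopropyl alcohol, with a difference of 0.399 in the first of these pairs and -0.066 in the second.

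**Figure D2:**
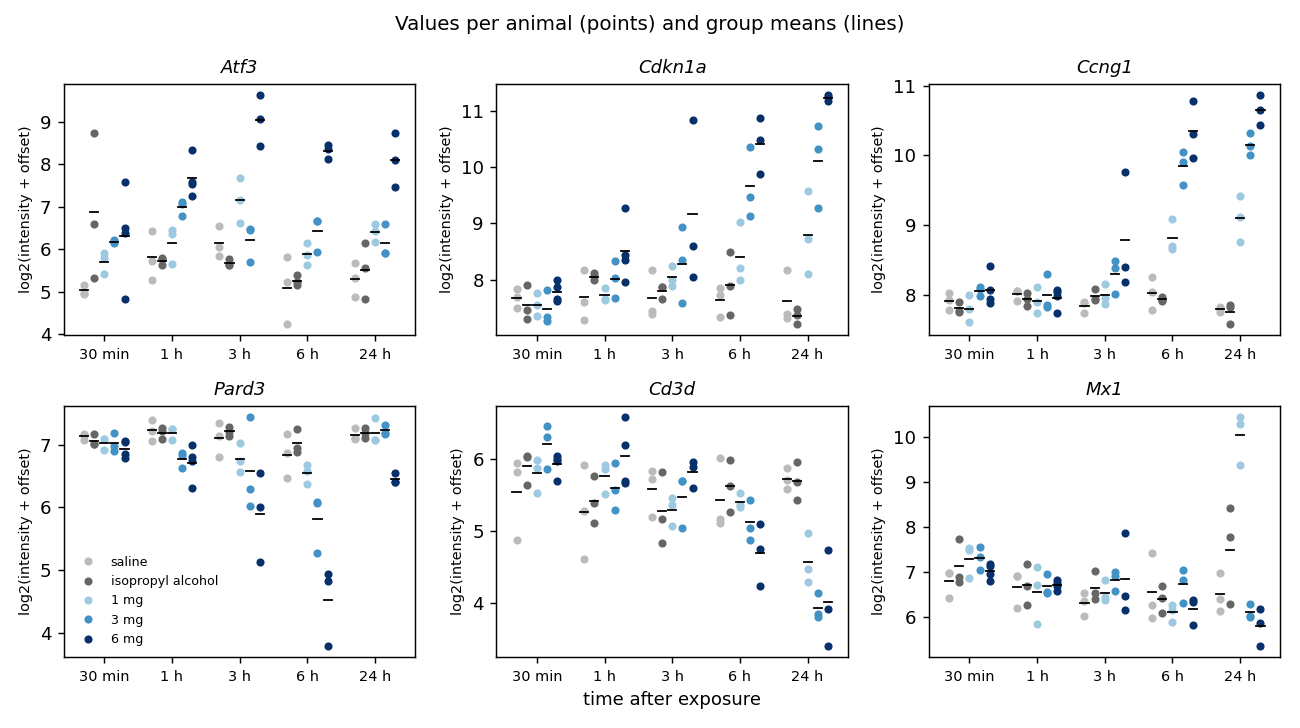
Values of Atf3, Cdkn1a, Ccng1, Pard3, Cd3d and Mx1 in each animal (points, log2 of intensity plus offset on the y axis) by time after exposure (x axis) and treatment (colour), with short lines for group means. The genes were picked for the plot after their values were seen, and Cdkn1a at 24 h averages an intensity of 2403 at 6 mg against 157.3 in isopropyl alcohol.

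At 6 h p53 target genes stood among the largest rises in the 6 mg animals against isopropyl alcohol (n = 3 each). Ccng1, which encodes cyclin G, a p53 target, rose 5.31-fold, from 239.6 ± 5.74 to 1335 ± 383 (SD), with a log2 fold change of 2.41 ± 0.21 (SE, adjusted p = 4.24e-13). Cdkn1a, which encodes the cell cycle inhibitor p21, rose 5.62-fold (2.49 ± 0.40), and Mdm2, the ubiquitin ligase of p53, rose 2.91-fold (1.54 ± 0.29). Atf3 rose 8.36-fold (3.06 ± 0.47), and Srxn1, which encodes the antioxidant sulfiredoxin, rose 3.97-fold (1.99 ± 0.52). Serpind1, Tubb6, Tnfrsf12a, the metallothionein gene Mt2A, the protease gene Adamts1, the cytokine gene Il1a and Hexim1, an inhibitor of transcription elongation, rose between 2.83-fold and 3.72-fold, and the other probe set of Il1a stood at a log2 fold change of 0.49.

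Pard3 had the largest named fall at 6 h, by 2.51 on the log2 scale (SE 0.24, adjusted p = 7.21e-12), from 124.6 ± 18.1 to 17.6 ± 8.94 (SD). Dock9, which encodes an exchange factor for Cdc42, fell by 2.04 (SE 0.18), whereas its other probe set had a log2 fold change of -0.53. Cdk14, a cyclin-dependent kinase gene, fell by 1.86 (SE 0.14, adjusted p = 3.1e-15), Plcb4, a phospholipase gene, fell by 1.96 (SE 0.24), and Map2k6, a kinase upstream of p38, fell by 1.92 (SE 0.21), to an intensity of 7.02 ± 2.49. Ttc28, Veph1, Arl15, Ankrd44, Mad1l1, Zdhhc14 and Atg10 fell between 3.45-fold and 4.76-fold.

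Of 16 p53 targets, 7 rose at 6 h (7 adjusted over the list alone), and the list median was 0.56 (camera, adjusted p = 5.26e-06, and adjusted p = 0.00113 with an estimated correlation). Of 25 oxidative stress and glutathione genes, 9 rose (9 adjusted over the list alone), with Hmox1 at 1.35 ± 0.28 and Gclc and Gclm, which encode the subunits of the enzyme that starts glutathione synthesis, at 1.03 ± 0.16 (other probe set 0.45) and 0.87 ± 0.16 (list adjusted p = 0.0353 with an estimated correlation). Other lists passed only with the preset correlation, of which heat shock genes and T and NK cell markers had an adjusted p of 0.0886 and 0.457 with scan days as a block. Adjusted p values with an estimated correlation were 0.311 for glucocorticoid-responsive genes (4 of 18 rose, and 4 rose and 1 fell adjusted over the list alone). They were 0.198 for hypoxia and glycolysis (3 rose and 1 fell of 18, the same numbers adjusted over the list alone). They were 0.557 with an estimated correlation for immediate early genes (4 of 19 rose, 4 adjusted over the list alone), heat shock genes (2 of 19 rose, 2 adjusted over the list alone) and T and NK cell markers (1 of 11 fell, 1 adjusted over the list alone). The T and NK cell member was Cd3d, at -0.92 ± 0.29 and an adjusted p of 0.0194, which became 0.174 with scan days as a block and was also lost without isopropyl alcohol replicate 2 or 6 mg replicate 3. That of Srxn1 was lost without isopropyl alcohol replicate 2. The block also ended the calls of the immediate early genes Klf6 and Ier3 (adjusted p = 0.079 and 0.322), of Hspa5 (0.159) among heat shock genes, of Dusp1 (0.13) and Glul (0.0525) among glucocorticoid-responsive genes and of Pgam1 (0.0524) among hypoxia genes. Other probe sets stood at 0.12 for Klf6, -0.12 for Dusp1, and -0.32 and -0.03 for Glul.

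No pair of scan days held 6 mg and isopropyl alcohol animals at 6 h. With scan days as a block 1494 probe sets changed, with Ccng1 at an adjusted p of 2.07e-09 and the p53 list at a median of 0.61. The count was 1254 without 6 mg replicate 2, 1182 with only the groups of that time in the fit and 3653 with array weights. The beta-actin 3'/5' log2 ratio was 1.64 ± 0.27 (SD) at 6 mg and 0.73 ± 0.31 in isopropyl alcohol (two-sided exact permutation p = 0.1, the smallest that 3 against 3 animals can give). All 3 of the 6 mg animals were scanned on the 9th and 10th scan days, where the ratios of the other 6 h animals were 1.96 in saline, 1.78 at 1 mg and 1.57 at 3 mg, and the isopropyl alcohol animals were scanned on other days.

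At 24 h p53 target genes were higher in the 6 mg animals than in isopropyl alcohol animals, and lymphocyte and smooth muscle genes were lower (n = 3 each). Cdkn1a rose 14.7-fold, from 157.3 ± 14.9 to 2403 ± 80.8 (SD), with a log2 fold change of 3.88 ± 0.40 (SE, adjusted p = 1.25e-10), and its other probe set stood at 3.35. Ccng1 rose 7.41-fold (2.89 ± 0.21, adjusted p = 3.67e-16), Mdm2 rose 4.78-fold (2.26 ± 0.29), and Phlda3, a p53-induced inhibitor of Akt signalling, rose 3.53-fold (1.82 ± 0.22). Atf3 (2.61 ± 0.47), Srxn1 (2.17 ± 0.52) and the tight junction gene Cldn4 (1.82 ± 0.29) rose. Ephx1, which encodes an epoxide hydrolase (1.78 ± 0.19), Akr1b8 (1.76 ± 0.49) and Il1r2, the decoy receptor of interleukin-1 (1.64 ± 0.39), also rose, as did Zfp688 and Dglucy.

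Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, fell by 3.10 at 24 h (SE 0.53, adjusted p = 3.36e-05), against isopropyl alcohol animals that varied widely (220.9 ± 226, SD). Its log2 fold change was -2.21 without isopropyl alcohol replicate 1 and -4.14 without replicate 3. Gzmm, a granzyme of cytotoxic lymphocytes, fell by 2.25 (SE 0.48), and Cd79b, part of the B cell receptor, fell by 2.09 (SE 0.31). Their intensities of 3.73 ± 1.35 and 3.92 ± 2.29 lay below the offset. Gzmm stood at -1.86 without isopropyl alcohol replicate 3 and at -2.88 without replicate 1. The mast cell protease gene Mcpt1 fell by 1.94 (SE 0.33), Wif1, an inhibitor of Wnt signalling, fell by 1.68 (SE 0.20), and Esm1, an endothelial gene, fell by 1.73 (SE 0.32). Acap1, Septin1, Nell1, Fcnb and the interferon-induced Mx1 fell between 3.22-fold and 3.67-fold. Mx1 stood at -1.22 without isopropyl alcohol replicate 2 and at -2.29 without replicate 3. Its log2 values at 24 h were 7.775, 8.417 and 6.282 in isopropyl alcohol and 6.984, 6.402 and 6.135 in saline. They were 6.184, 5.359 and 5.875 at 6 mg. A fall after the agent and high values of these control animals thus cannot be told apart for Mx1. Cyp26b1, an enzyme that breaks down retinoic acid, fell by 2.03 (SE 0.57, adjusted p = 0.0165), and its adjusted p was 0.104 with scan days as a block.

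Of 16 p53 targets, 9 rose at 24 h (9 rose and 1 fell adjusted over the list alone), with a median of 0.65 (camera, adjusted p = 1.79e-14, and adjusted p = 2.09e-07 with an estimated correlation). Of 11 T and NK cell markers, 8 fell (10 adjusted over the list alone), Cd3d by 1.67 (SE 0.29), Cd3g by 1.45 (SE 0.19), Klrd1 by 1.36 (SE 0.19) and Lck by 1.20 (SE 0.19) among them. The list had a median of -1.19 (adjusted p = 0.00253 with an estimated correlation). Of the 18 symbols on the B and plasma cell list only 4 were measured. Of these 4, 3 fell (3 adjusted over the list alone), Cd79b, Cd37 and Cd74, with a list median of -0.77 (adjusted p = 0.00335 with an estimated correlation). Of 11 smooth muscle genes, 7 fell (10 adjusted over the list alone), Myh11 by 1.02 (SE 0.18), Actg2 by 0.90 (SE 0.21) and Mylk by 0.54 (SE 0.11) among them. The list had a median of -0.64 (adjusted p = 0.00386 with an estimated correlation). Of 25 oxidative stress genes, 5 rose (8 rose and 1 fell adjusted over the list alone), including the glutathione transferase genes Gstp1 (1.16 ± 0.21) and Gsta1 (1.16 ± 0.15) (list adjusted p = 0.00499 with an estimated correlation). Of 18 hypoxia and glycolysis genes, Aldoa, Ldha and Pgam1 rose, 3 also adjusted over the list alone (list adjusted p = 0.047 with an estimated correlation).

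Further lists at 24 h passed only with the preset correlation. The alveolar type I cell list had a median of -0.31, with the water channel gene Aqp5 (-0.93 ± 0.19) and Emp2 (-0.39 ± 0.12) lower among 10 members, 2 also adjusted over the list alone, and an adjusted p of 0.065 with an estimated correlation. Glucocorticoid-responsive genes (3 of 18 rose, 5 adjusted over the list alone) and immediate early genes (4 of 19 rose, and 9 rose and 1 fell adjusted over the list alone) had an adjusted p of 0.11 with an estimated correlation. The iron, copper and acute phase list, in which Serpina3n (1.60 ± 0.47, and 0.99 without 6 mg replicate 2) and Cp, which encodes ceruloplasmin (0.54 ± 0.17), rose among 11 members (4 rose and 1 fell adjusted over the list alone), had an adjusted p of 0.0687 with an estimated correlation.

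The 24 h count was 767 with scan days as a block, 454 without 6 mg replicate 1 and 1174 with array weights, and with the block the adjusted p of Cd37 was 0.122, that of Emp2 was 0.0779 and those of the glucocorticoid-responsive or immediate early genes Fkbp5, Junb and Ier3 were 0.0765, 0.0785 and 0.131. Akr1b8, Cyp26b1, Fcnb, Cd37, Emp2, Aldoa, Ldha, Pgam1, Serpina3n and Cp lost their calls in 1 or more of the fits without an animal, and the hypoxia median of 0.27 was 0.18 without isopropyl alcohol replicate 3. In the pair of scan days that held both groups (1 animal each) the list medians were 0.74 for p53 targets and -0.91 for T and NK cell markers. They were -0.68 for B cell markers and -0.89 for smooth muscle. They were 0.28 for oxidative stress, 0.33 for hypoxia, -0.21 for alveolar type I cells, 0.44 for glucocorticoid-responsive, 0.55 for immediate early and 0.36 for acute phase genes. The GAPDH 3'/5' log2 ratio at 24 h was 1.23 ± 0.36 (SD) at 6 mg and 0.76 ± 0.42 in isopropyl alcohol, and 0.81 and 0.90 for the 2 animals of that pair.

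**Figure D3:**
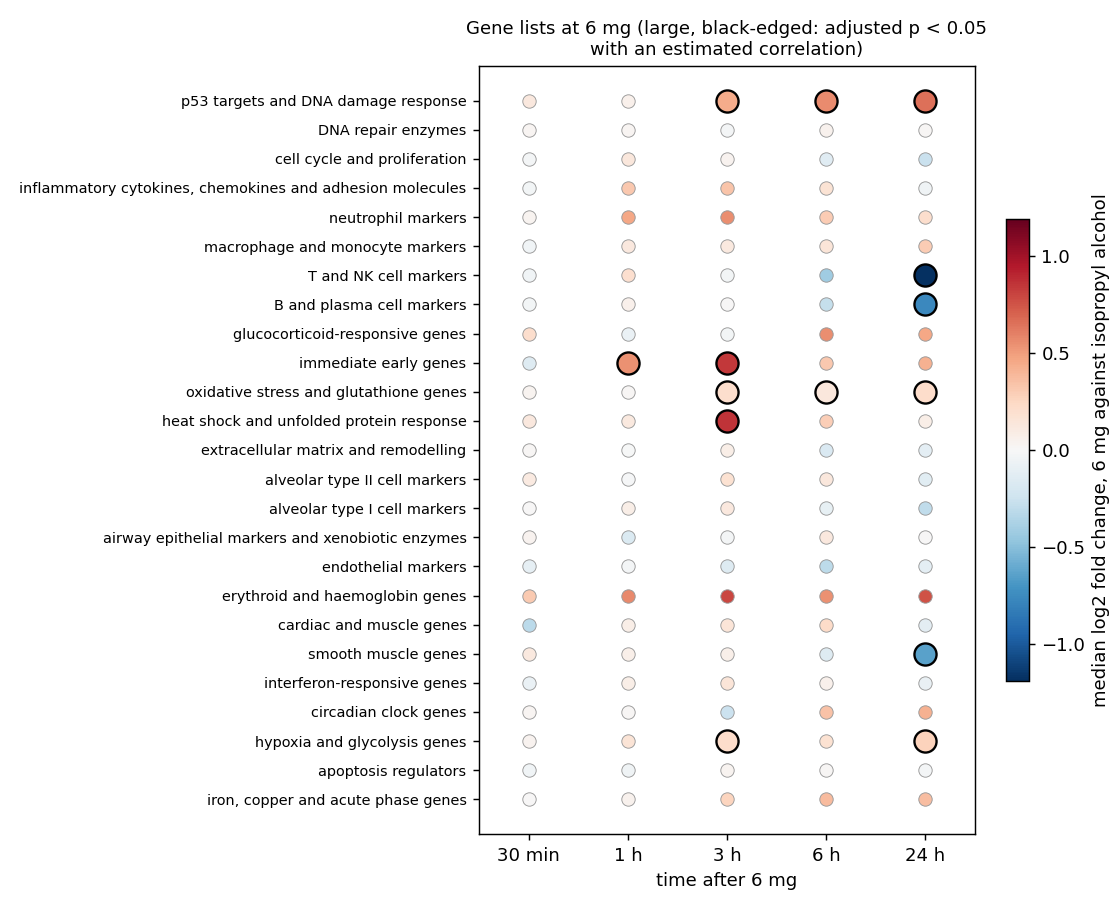
Median log2 fold change (colour) of each of 25 gene lists (y axis) in 6 mg against isopropyl alcohol animals at each time after exposure (x axis). Large, black-edged points had an adjusted p under 0.05 with an estimated correlation, and the T and NK cell markers at 24 h lie at -1.19.

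Whether the 6 mg effect differed between times was tested itself, and it did for 1270 probe sets (limma F-test, adjusted p under 0.05). Ccng1 had the smallest adjusted p (2.76e-12), with log2 fold changes of 0.02 ± 0.19 (SE) at 1 h and 2.89 ± 0.21 at 24 h. Cdk14 (adjusted p = 1.04e-09) was at -1.86 ± 0.14 at 6 h and -0.81 ± 0.14 at 24 h. Fat1, a cadherin gene, was at -0.56 ± 0.14 at 3 h and 1.09 ± 0.14 at 24 h, and Plat, which encodes tissue plasminogen activator, was at -0.04 ± 0.14 at 3 h and 1.12 ± 0.14 at 24 h. Fto was at -1.44 ± 0.13 at 6 h and -0.44 ± 0.13 at 24 h, and Dock9 was at -2.04 ± 0.18 and -0.33 ± 0.18. With scan days as a block 1216 probe sets differed, and the count was 758 on chip B alone and 2309 with array weights.

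The next question was how the response depended on dose. In 3 mg animals (n = 3 each against isopropyl alcohol) 0 probe sets changed at 30 min, 1 h and 3 h by limma, beside 145, 363 and 508 with an unadjusted p under 0.05, fewer than chance gives. With array weights these counts were 4, 1 and 26, the 30 min count was 1 without isopropyl alcohol replicate 1, and the 3 h count was 8 without 3 mg replicate 3 and 1 without 3 mg replicate 1. Lists at 3 mg that passed at these times did so only with the preset correlation. The adjusted p with an estimated correlation was 0.407 for immediate early genes at 30 min, among them Junb at -0.88 ± 0.30 and Egr1 at -0.92 ± 0.38, and 0.425 for the T and NK cell, erythroid, cardiac and smooth muscle lists. At 1 h it was 0.198 for the cell cycle, inflammatory, neutrophil and immediate early lists, with S100a8, a neutrophil gene, at a fold of 2.83 and an adjusted p of 1, and 0.619 for heat shock genes. Adjusted over the list alone, 2 of 5 neutrophil, 1 of 17 inflammatory and 1 of 19 immediate early genes were higher at 1 h. The isopropyl alcohol animals of 30 min, the control there, stood above saline on the immediate early list, as given below.

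At 6 h p53 targets rose after 3 mg, and larger numbers of probe sets fell than rose (36 higher, 151 lower, n = 3 each). Ccng1 rose 3.74-fold (log2 fold change 1.90 ± 0.21, adjusted p = 1.2e-09), Cdkn1a 3.35-fold (1.74 ± 0.40) and Mdm2 2.27-fold (1.18 ± 0.29), and Tmed1 and Phlda3 rose by 0.95 ± 0.21 and 0.83 ± 0.22. The receptor phosphatase gene Ptprm fell by 1.83 (SE 0.24, adjusted p = 5.91e-07), the phospholipase gene Plcb1 fell by 1.43 (SE 0.23) and Lrba fell by 1.28 (SE 0.14), as did Fggy and Fars2 by 1.38 and 1.27. Of 16 p53 targets, 5 rose (6 adjusted over the list alone), with an adjusted p of 6.28e-05 with an estimated correlation. T and NK cell markers had a median of -0.44 with 0 of 11 past the test and 1 lower when adjusted over the list alone (list adjusted p = 1.45e-05, and adjusted p = 0.244 with an estimated correlation). The 187 changed probe sets became 202 with scan days as a block. They became 97, 101, 117 and 120 without 3 mg replicate 1, isopropyl alcohol replicate 1, 3 mg replicate 2 or isopropyl alcohol replicate 3. They became 42 with only the groups of that time, 111 and 117 on chip A or B alone and 643 with array weights. Cdkn1a, Mdm2, Tmed1, Phlda3, Fggy and Fars2 each lost the call without 1 or more of the animals. In the pair of scan days that held both groups (1 animal each) the list medians were 0.32 for p53 targets and -0.19 for T and NK cell markers.

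At 24 h p53 targets were higher and lymphocyte markers lower after 3 mg, with 28 probe sets higher and 28 lower (n = 3 each). Cdkn1a rose 6.75-fold, to 1195 ± 548 (SD), with a log2 fold change of 2.76 ± 0.40 (SE, adjusted p = 8.74e-06), Ccng1 rose 5.25-fold (2.39 ± 0.21), Mdm2 rose 2.86-fold (1.52 ± 0.29), and Ephx1 and Ly6i rose 2.76-fold and 2.53-fold. Cyp1a1 fell by 2.81 (SE 0.53, with -1.92 without isopropyl alcohol replicate 1 and -3.86 without replicate 3). Cd3d fell by 1.76 (SE 0.29), Gzmm fell by 2.07 (SE 0.48), Acap1 fell 2.83-fold (adjusted p = 0.00765), and Cd79b fell by 1.39 (SE 0.31). Gzmm stood at -1.68 without isopropyl alcohol replicate 3 and at -2.70 without replicate 1. Of 16 p53 targets, 6 rose (6 adjusted over the list alone, list adjusted p = 2.21e-07 with an estimated correlation). Of 11 T and NK cell markers, Cd3d, Cd3g and Lck fell, 3 over all genes and 6 adjusted over the list alone, with a median of -0.58 (adjusted p = 0.000486 with an estimated correlation). Of 4 B cell markers, 2 fell (3 adjusted over the list alone, adjusted p = 3.46e-05 with an estimated correlation). Of 25 oxidative stress genes 1, Gsta1, rose by 0.79 ± 0.15 (2 adjusted over the list alone, adjusted p = 0.0135 with an estimated correlation). The interferon list, with Mx1 at -1.38 ± 0.36 and an adjusted p of 0.0601 and 3 of 18 members lower when adjusted over the list alone, had an adjusted p of 0.123 with an estimated correlation, as did the circadian clock list. The isopropyl alcohol animals were those whose Mx1 values are given above, so high controls cannot be told apart from a fall of Mx1 here either. The cell cycle and smooth muscle lists had an adjusted p of 0.509 and 0.481 with an estimated correlation.

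The count of 56 at 24 h after 3 mg became 34 with scan days as a block, 24 and 32 without 3 mg replicate 1 or 3, 34 on chip A alone, 35 with only the groups of that time and 105 with array weights. With the block the adjusted p of Cd79b, Gzmm, Cd37 and Gsta1 was 0.209, 0.217, 0.247 and 0.066. The calls of Cyp1a1, Gzmm, Acap1, Cd79b, Lck and Gsta1 were also lost without 1 or more of the animals. In the pair of scan days that held both groups (1 animal each) the list medians were 0.42 for p53 targets and -0.57 for T and NK cell markers. They were -0.58 for B cell markers and 0.18 for oxidative stress genes.

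The difference between 6 and 3 mg at 24 h was tested itself (n = 3 each), and 24 probe sets were higher and 98 lower at 6 mg. Atf3 was 3.91-fold higher (1.97 ± 0.47, adjusted p = 0.0147), and Plat was 1.94-fold higher (0.96 ± 0.14, adjusted p = 4.95e-06). Epha2, an ephrin receptor gene, was 1.94-fold higher (0.96 ± 0.15), with Ube2g2 and the endothelial protein C receptor gene Procr 1.73-fold and 1.72-fold higher. Ptprm (-1.35 ± 0.24), Atrnl1 (-1.31 ± 0.15, adjusted p = 1.06e-07), Wif1 (-1.18 ± 0.20), the laminin gene Lama2 (-1.14 ± 0.26) and the claudin gene Cldn11 (-1.14 ± 0.19, with another probe set at -0.39) were lower. The 122 probe sets became 97 with scan days as a block, 60 and 68 without 6 mg replicate 1 or 2, 54 and 54 without 3 mg replicate 2 or 3. They became 59 on chip B alone, 67 with only the groups of that time, 188 with 3'/5' ratios as covariates and 682 with array weights. Atf3, Ube2g2, Procr and Lama2 each lost the call without 1 or more of the animals.

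After 1 mg (n = 3 each) 0 probe sets changed at 30 min and 1 h by limma, beside 114 and 402 with an unadjusted p under 0.05, fewer than chance gives. The 30 min count was 9 with array weights and 1 without isopropyl alcohol replicate 1. At 30 min immediate early genes had a median of -0.28, with Junb at -0.99 ± 0.30 (SE) and Egr1 at a level 0.5 times that in isopropyl alcohol, 0 of 19 past the test and 1 lower when adjusted over the list alone. The list had an adjusted p of 0.0408 with an estimated correlation (camera, and a median of -0.44 in the pair of scan days that held both groups, and of -0.09 without isopropyl alcohol replicate 1). On this list the same isopropyl alcohol animals stood above saline at 30 min, as given below. At 3 h Pelo rose by 0.66 ± 0.13 (adjusted p = 0.0259) and Klf15, a transcription factor induced by glucocorticoids, fell 2.64-fold, from 463.3 ± 35.6 to 174.1 ± 36.7 (SD, adjusted p = 0.0259). Both calls were lost with scan days as a block (adjusted p 0.153 and 0.161), and no pair of scan days held both groups. The count of 2 was 0 without 1 mg replicate 1 or 2 or without isopropyl alcohol replicate 1, 2 or 3, and 105 with array weights. At 6 h 1 probe set, for which no gene was listed, passed with a log2 fold change of -0.74 (adjusted p = 0.0134). Its value was seen before it was picked for mention, and the call was absent without 1 mg replicate 1 or 3 or without isopropyl alcohol replicate 1, 2 or 3. Further lists passed only with the preset correlation, with an adjusted p of 0.997 for cardiac genes at 30 min, 0.488 for glucocorticoid-responsive genes at 1 h, each with an estimated correlation. They were 0.462 for those and for immediate early genes at 3 h (3 of 19 higher when adjusted over the list alone), 0.32 for oxidative stress genes at 3 h and 0.297 for T and NK cell markers at 6 h, each with an estimated correlation.

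At 24 h after 1 mg, interferon-induced genes were higher than in isopropyl alcohol animals (n = 3 each), and 36 probe sets were higher and 1 lower. Rsad2, which encodes the antiviral protein viperin, rose 7.23-fold, from 207.1 ± 173 to 1263 ± 439 (SD), with a log2 fold change of 2.86 ± 0.32 (SE, adjusted p = 2.36e-08). Mx1, an antiviral GTPase, rose 5.87-fold (2.55 ± 0.36), Usp18, which removes the ubiquitin-like protein ISG15, rose 4.11-fold (2.04 ± 0.35), the chemokine gene Cxcl10 rose 3.60-fold (1.85 ± 0.32), and the class I antigen gene RT1-T24-3 rose 6.27-fold (2.65 ± 0.63). Without isopropyl alcohol replicate 3 the log2 fold changes of Rsad2, Mx1 and Usp18 were 2.221, 1.948 and 1.302, and without replicate 2 those of Rsad2, Usp18 and RT1-T24-3 were 3.49, 2.63 and 1.93. Of 18 interferon-responsive genes, 7 rose (10 rose and 1 fell adjusted over the list alone), Ifit3 by 1.80 ± 0.29, Oas1a by 1.53 ± 0.26 and Gbp2 by 1.27 ± 0.22 among them. The list had a median of 0.50 (camera, adjusted p = 1.48e-19, and adjusted p = 0.00205 with an estimated correlation). Ccng1 rose by 1.34 ± 0.21 (adjusted p = 6.71e-05), and Cd3g, part of the T cell receptor complex, fell by 0.89 (SE 0.19, adjusted p = 0.0089, and 0.0882 with scan days as a block). The other lists that passed only with the preset correlation were p53 targets (1 of 16 rose, 2 adjusted over the list alone, adjusted p = 0.0847 with an estimated correlation), T and NK cells (1 of 11 fell, 4 adjusted over the list alone, 0.136) and B cells (1 of 4 lower adjusted over the list alone, 0.098). Others were glucocorticoid-responsive (adjusted p = 0.463 with an estimated correlation), heat shock (0.492) and extracellular matrix genes (0.43).

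The count of 37 at 24 h after 1 mg became 30 with scan days as a block, 13 without isopropyl alcohol replicate 3, 20 and 24 without 1 mg replicate 1 or 3, 24 on chip A alone and 1 with only the groups of that time. It was 17 without the 3 animals of the 13th and 14th scan days, where the adjusted p of Usp18 was 0.0814 and that of RT1-T24-3 was 0.0935. RT1-T24-3, Usp18, Cd3g and Oas1a each lost the call without 1 or more of the animals. In the pair of scan days that held both groups (1 animal each) the interferon list median was 0.65, and its 1 mg animal had the highest list value of the animals given 1 mg.

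A linear trend over 0, 1, 3 and 6 mg was fitted at each time, as a slope of log2 intensity per mg. The 6 mg group has the largest weight in this slope, so a change at 6 mg alone can pass. At 3 h 2, 0 and 1437 probe sets changed after 1, 3 and 6 mg against isopropyl alcohol. A passing trend thus does not show a graded response. The trend passed for 0 probe sets at 30 min (limma, 664 with an unadjusted p under 0.05), 53 at 1 h (31 higher with dose, 22 lower), 1345 at 3 h (359 and 986), 2265 at 6 h (890 and 1375) and 901 at 24 h (373 and 528). With scan days as a block these were 2, 0, 1370, 1936 and 985. The 30 min count was 6 without 6 mg replicate 1 and 1 without isopropyl alcohol replicate 2. The 1 h count was between 17 and 33 without isopropyl alcohol replicate 1 (22) or 2 (20), 1 mg replicate 1 (24) or 6 mg replicate 1 (33), 2 (17) or 3 (30). The counts at 3, 6 and 24 h were 237 without 6 mg replicate 3, 1417 without 6 mg replicate 2 and 573 without 6 mg replicate 1.

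The last question was what isopropyl alcohol did against saline (n = 3 each). At 30 min immediate early genes were higher, with Egr1 up 3.94-fold (log2 fold change 1.98 ± 0.38, adjusted p = 0.015), Nr4a1 up 3.77-fold (1.91 ± 0.32, adjusted p = 0.00192) and Junb up 2.75-fold (1.46 ± 0.30, adjusted p = 0.0351, and 0.0727 with scan days as a block). Of 19 immediate early genes these 3 rose (8 adjusted over the list alone), with a median of 0.39 (camera, adjusted p = 3.6e-22, and adjusted p = 0.000248 with an estimated correlation). The pair of scan days that held both groups gave a list median of 0.62. In that pair, against the same isopropyl alcohol animals, the list median was -0.44 at 1 mg and -0.38 at 3 mg. Those doses were also given in isopropyl alcohol. An effect of isopropyl alcohol, an opposite effect of the low doses and high values of these control animals thus cannot be told apart at 30 min. Without isopropyl alcohol replicate 1 Egr1 stood at 1.37, and without replicate 3 the list median was 0.62. At 3 h Hmox1 rose 2.95-fold, from 112.4 ± 8.57 to 356.2 ± 106 (SD, adjusted p = 0.00842, and 0.217 with scan days as a block). At 6 h Rabepk (1.01 ± 0.18) and the nucleoside transporter gene Slc29a1 (0.68 ± 0.13) rose, both with an adjusted p of 0.00726 (limma). Without the 3 animals of the 13th and 14th scan days both calls were lost (adjusted p 0.3 and 0.122).

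At 1 h and 24 h 0 probe sets changed by limma after isopropyl alcohol, and the 24 h count was 1 without saline replicate 2. There were 189 and 317 with an unadjusted p under 0.05, fewer than chance gives. At 1 h the neutrophil list had a median of -1.15, with S100a9 at -1.63 ± 0.53 (SE), 0 of 5 members past the test and 3 lower when adjusted over the list alone (adjusted p = 0.0317 with an estimated correlation). Its median was -1.82 and -0.63 in the 2 pairs of scan days that held both groups (2 against 2 and 1 against 1 animal). It was 0.06 with no filter on low probe sets. Lists that passed only with the preset correlation had an adjusted p, with an estimated correlation, of 0.503 (erythroid) and 0.603 (interferon) at 30 min. At 1 h it was 0.204 (macrophage, oxidative stress), 0.251 (erythroid) and 0.561 (T and NK cells). It lay between 0.156 and 0.412 for 8 lists at 3 h and was 0.752 (interferon) at 24 h, where Mx1 stood at 0.98 ± 0.36 with an adjusted p of 1.

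The isopropyl alcohol counts were small and moved with single animals. The count of 3 at 30 min was 0 without isopropyl alcohol replicate 1 or saline replicate 1, 1 without saline replicate 2, 5 without isopropyl alcohol replicate 3 and 26 with array weights. That of 1 at 3 h was 0 without isopropyl alcohol replicate 1 or 2 or saline replicate 1 or 2. That of 2 at 6 h was 0 without saline replicate 2, 214 without saline replicate 1, 146 without saline replicate 3 and 440 with array weights.

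Averaged within times, the GAPDH 3'/5' log2 ratio of control probe sets was higher at 6 mg by 0.40 and that of beta-actin by 0.48 (17 and 15 animals, two-sided permutation p = 0.00574 and 0.0193 with 100000 permutations within times, which took no account of scan days). In the 5 pairs of scan days that held both groups at a time, the difference in GAPDH ratio was 0.399 and -0.066 at 3 h, 0.329 and -0.09 at 30 min and -0.085 at 24 h. That in beta-actin was 0.348 and -0.104 at 3 h, 0.231 and -0.227 at 30 min and 0.022 at 24 h. The first principal component of all animals (25.1% of the variance) had a correlation of 0.855 with the GAPDH ratio, with 81.9% of it explained by pairs of scan days and 65.4% by groups. At single times the exact permutation p lay between 0.1 and 0.771, and the adjusted p over the 10 comparisons was 0.5 or more.

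**Figure D4:**
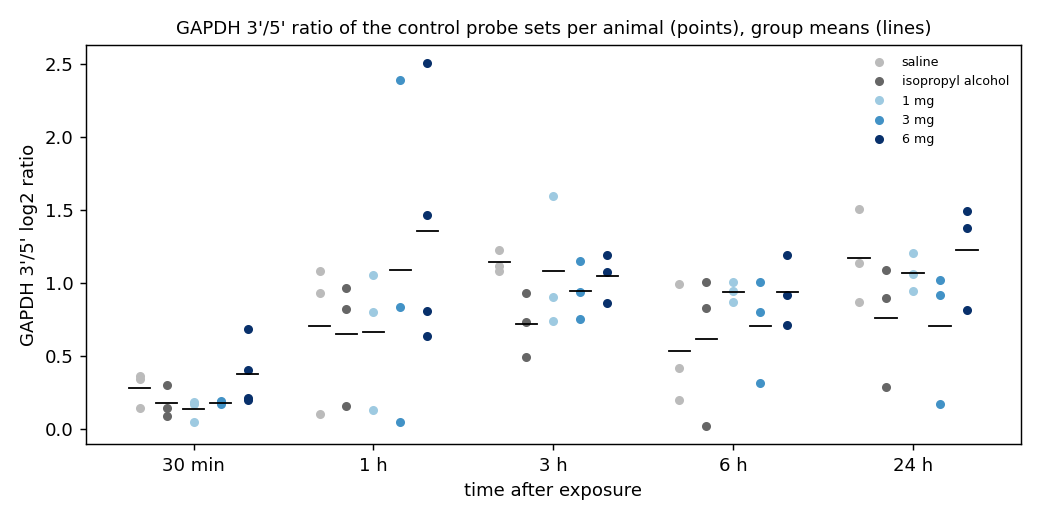
GAPDH 3'/5' log2 ratio of the control probe sets in each animal (points, y axis) by time after exposure (x axis) and treatment (colour), with short lines for group means. At 1 h the 6 mg animals average 1.36 and the isopropyl alcohol animals 0.65, and the mean of each treatment is lowest at 30 min. All 30 min animals were scanned on the 15th to 17th scan days. Of other times only 3 mg replicate 3 at 24 h was scanned on these days, with a ratio of 0.167 against 1.024 and 0.921 in its group. Time and scan day thus cannot be told apart for 30 min.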

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

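The tests of scan days and of single animals for the interferon list, and of dilution by other cells for the lymphocyte markers, were chosen only after those results were seen, and the count of list shifts with an estimated correlation under other splits was added after the count with the preset correlation was seen, though before its own value was. The difference in 6 mg effect between times was picked out because effects under the same contrast differed by an F-test, for 1270 probe sets. For the 10 genes with the smallest p of that test, the widest difference between any 2 times on the log2 scale was 2.867 for Ccng1, 2.057 for Dock9, 2.196 for Ephx1, 1.872 for Cdk14 and 1.795 for Dglucy, and 1.673 for Epha2, 1.645 for Fat1, 1.527 for Slc27a3, 1.426 for Fto and 1.167 for Plat. The control probe sets, which no comparison uses, were picked out because the 3'/5' log2 ratio was higher at 6 mg than in isopropyl alcohol animals, by 0.404 for GAPDH and by 0.48 for beta-actin, averaged within times with no account of scan days. In the groups of 4 animals, 16 items were tested for an animal far from the others by Dixon's test, and none was above its critical value (highest gap over range 0.814, for Ier3).

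The 13 rises and 8 falls at 1 h after 6 mg, 3 of the rises in genes of the immediate early list, might reflect RNA integrity or scan days, since the groups shared no pair of scan days. With the 3'/5' ratios as covariates the 21 probe sets kept 97% of their median log2 fold change, taken with the sign of falls reversed (0.81 before, 0.79 after, median SE 0.18 and 0.19), and 8 probe sets passed. With scan days as a block they kept 88% (0.81 before, 0.71 after), but the median SE rose from 0.18 to 0.23 and 0 probe sets passed. That fit left 6 mg replicate 1, alone on its pair of scan days, without weight. The median thus moved little while the error grew, but single genes moved more, Ppp1r18 from 0.70 to 0.33 and Ppp1r15a from 0.98 to 0.65. An effect of the agent and an effect of scan day cannot be told apart gene by gene at this time.

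The higher interferon-responsive genes at 24 h after 1 mg might come from scan days, RNA integrity or a single animal. With scan days as a block the list kept 111% of its median (0.50 before, 0.56 after, adjusted p = 0.000815 with an estimated correlation), with the ratios as covariates 109% (0.55, adjusted p = 0.000146 with an estimated correlation), and without any of the 3 animals given 1 mg at least 75.9%. Without any 1 animal of either group the median lay between 0.38 and 0.69, so that none of these 3 explanations alone accounts for the shift of the list, although the count of probe sets was 13 without isopropyl alcohol replicate 3. The difference between 1 mg and the other doses was not tested, and no biological explanation was tested.

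The lower T, NK and B cell markers at 24 h after 6 mg might come from RNA integrity, scan days or dilution by RNA of other cells. The markers kept 91.5% of their median fall with the ratios as covariates (-0.92 before, -0.84 after, adjusted p = 0.00204 for T and NK cells with an estimated correlation) and 84.6% with scan days as a block (-0.78, adjusted p = 0.0037 with an estimated correlation). Dilution would lower markers of other resident cells alike. The medians were -0.11 for endothelial, -0.31 for alveolar type I and -0.14 for alveolar type II markers, with lower quartiles of -0.52, -0.39 and -0.32. The macrophage median was 0.30, -32.7% of the lymphocyte fall. It cannot decide the question, since macrophages could be among the diluting cells. Smooth muscle genes, not among these 4 lists, had a median of -0.64 (7 of 11 fell, adjusted p = 0.00386 with an estimated correlation). The endothelial and alveolar lists fell less than the lymphocyte markers, so equal dilution of all resident cells does not account for the whole fall. A part of the fall through dilution stays open. A loss of lymphocytes from the lung is a hypothesis, and cell counts were not analysed here.

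Each count was also computed for other divisions of the same animals into groups, which took no account of scan days. For 6 mg at 30 min 35 of 35 divisions gave a count as large as the real 0 (highest other 4). A real count of 0 fixes such an outcome in advance, here and below, so it decides nothing. For 6 mg at 1 h 1 of 35 divisions gave a count as large, the real one (21, highest other 9). No pair of scan days held treated and isopropyl alcohol animals for 6 mg at 1 h and 6 h or for 1 mg at 3 h. The divisions there cannot tell an effect of the agent from one of scan day. With 3 against 3 animals 10 divisions are too few for a share under 0.05. The real count and the highest other were 1437 and 286 for 6 mg at 3 h, 2025 and 0 at 6 h, and 747 and 2 at 24 h. They were 187 and 13 for 3 mg at 6 h, 56 and 2 at 24 h, 2 and 0 for 1 mg at 3 h, 1 and 0 at 6 h, and 37 and 11 at 24 h. They were 3 and 0 for isopropyl alcohol at 30 min, 1 and 0 at 3 h, and 122 and 0 for 6 against 3 mg, each with 1 of 10 as large. All 10 divisions were as large where the real count was 0, with the highest other 0, 0 and 2 for 3 mg at 30 min, 1 h and 3 h, 0 and 1 for 1 mg at 30 min and 1 h, and 5 and 7 for isopropyl alcohol at 1 h and 24 h. For isopropyl alcohol at 6 h 6 of 10 were as large (2, highest other 11). Of 100 divisions, the dose trend was as large in 100 at 30 min (0, highest other 1), 3 at 1 h (53, 262), 1 at 3 h (1345, 1195), 1 at 6 h (2265, 1028) and 1 at 24 h (901, 733), and the difference between times in 4 (1270, 1948). List shifts with the preset correlation were as many in 38 of 100 (78, median other 72, highest other 110), so that chance could give as many. With an estimated correlation they were as many in 1 of 100 (23, median other 3, highest other 12).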

How the results depend on the processing

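The fits with 3'/5' ratios as covariates and without 3 animals were chosen only after the data were seen. The genes under other observations were not run under the alternatives, and 147 of the 192 gene results that were run remained with the lowest 50% left out. None of the 192 reversed where it was run. Of these, the call was lost in 1 with all arrays, 2 and 6 with the offset at the 1st and 40th percentile, 8 with a floor. It was lost in 15 with no filter, 15 with array weights, 16 with covariates, 19 with quantile normalization, 23 and 42 with chip A or B alone, 26 without 3 animals, 34 with scan days as a block and 55 with only the groups of that time. Of 78 list shifts with the preset correlation, 23 also passed with an estimated correlation. Alternatives were run for 36 of the 78, of which 13 were lost with an estimated correlation, 6 with the lowest 50% left out, 4 with quantile normalization and 3 with scan days as a block. The neutrophil list after isopropyl alcohol at 1 h reversed from -1.154 to 0.057 with no filter. List tests were not run with all arrays. In the 11 comparisons with 10 or more changed probe sets under both scalings, quantile normalization moved the share of higher probe sets by under 10 points, and for 6 mg at 1 h the share was not computed. For 6 mg at 3 h quantile normalization gave 382 higher and 672 lower probe sets, against 426 and 1011. The excess of falls at 3 h thus depended in part on the scaling. Intensities near the offset limit what falls of weakly expressed genes can show. Causes of the moved counts below were not tested, except that fewer arrays or animals were fitted where some were left out.

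Counts over 1.5 times away from those reported are given by setting. With array weights they were, for 6 mg, 27 at 30 min, 748 at 3 h, 3653 at 6 h and 1174 at 24 h. For 3 mg they were 4 at 30 min, 1 at 1 h, 26 at 3 h, 643 at 6 h and 105 at 24 h, and for 1 mg 9 at 30 min, 105 at 3 h and 6 at 6 h. For isopropyl alcohol they were 26 at 30 min, 8 at 3 h and 440 at 6 h. For the trend they were 24 at 30 min, 617 at 3 h, 3618 at 6 h and 1494 at 24 h, and 682 for 6 against 3 mg and 2309 for the difference between times. With only the groups of that time they were, for 6 mg, 4 at 1 h, 453 at 3 h and 1182 at 6 h, and for 3 mg 42 at 6 h and 35 at 24 h. For 1 mg they were 0 at 3 h, 0 at 6 h and 1 at 24 h. For isopropyl alcohol they were 1 at 30 min, 0 at 3 h and 0 at 6 h. For the trend they were 1 at 30 min, 5 at 1 h, 514 at 3 h and 1435 at 6 h, and 67 for 6 against 3 mg.

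On chip A alone they were 11 for 6 mg at 1 h, 111 and 34 for 3 mg at 6 and 24 h, 5, 0 and 24 for 1 mg at 3, 6 and 24 h, 0 and 6 for isopropyl alcohol at 3 and 6 h and 18 for the trend at 1 h. On chip B alone they were 2 and 882 for 6 mg at 1 and 3 h, 117 for 3 mg at 6 h, 0 and 0 for 1 mg at 3 and 6 h, 2 and 0 for isopropyl alcohol at 3 and 6 h, 842 for the trend at 3 h, 59 for 6 against 3 mg and 758 for the difference between times. The block of scan days gave 0 for 6 mg at 1 h, 34 for 3 mg at 24 h, 1 for 1 mg at 3 h, 0 and 6 for isopropyl alcohol at 3 and 6 h, and 2 and 0 for the trend at 30 min and 1 h. With covariates they were 8 for 6 mg at 1 h, 0 for 1 mg at 3 h, 4 for isopropyl alcohol at 6 h, 27 for the trend at 1 h and 188 for 6 against 3 mg. Without the 3 animals they were 17 for 1 mg at 24 h, 2 and 0 for isopropyl alcohol at 3 and 6 h and 1 for the trend at 30 min. No filter gave 6 for 6 mg at 1 h and 31 for the trend at 1 h. Quantile normalization gave 9 for 6 mg at 1 h and 0 for 1 mg at 6 h. The 40th percentile offset and the filter of 50% each gave 2 for isopropyl alcohol at 3 h, and the 1st percentile offset gave 4 for it at 6 h. List shifts numbered 23 with an estimated correlation, against 78.

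With all arrays, the chip letter as a replicate block and the animal as a random block, counts were 12 and 243 for 6 mg at 30 min and 1 h, 2, 2 and 118 for 3 mg at 1, 3 and 24 h, and 54 and 71 for 1 mg at 3 and 24 h. They were 7, 1, 3 and 20 for isopropyl alcohol at 30 min, 1, 3 and 6 h, 19 and 370 for the trend at 30 min and 1 h, and 264 for 6 against 3 mg. The block moved no other count by over 1.5 times. Chip letters did not pair the arrays of different animals, since the correlation of deviations over 300 pairs of groups had a median of 0.04 (-0.25 to 0.503) with 89 above 0.1.

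Leaving out each animal gave, as lowest and highest, 0 to 1, 3 to 13, 285 to 1835, 1254 to 1755 and 454 to 650 for 6 mg at 30 min and 1, 3, 6 and 24 h. For 3 mg the ranges were 0 to 1, 0 to 0, 0 to 8, 97 to 189 and 24 to 50. For 1 mg they were 0 to 1, 0 to 0, 0 to 3, 0 to 1 and 13 to 52. For isopropyl alcohol they were 0 to 5, 0 to 0, 0 to 1, 0 to 214 and 0 to 1, and for the trend 0 to 6, 17 to 68, 237 to 1733, 1417 to 2290 and 573 to 908. They were 54 to 94 for 6 against 3 mg, 937 to 1587 for the difference between times and 73 to 86 for list shifts.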

Other observations

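The genes below were named by the rule, and no test was chosen after seeing them. DNA repair enzymes held 21 measured members at 6 mg, with list adjusted p values of 0.889, 0.81 and 0.926 with an estimated correlation at 3, 6 and 24 h (n = 3 each). Mgmt, which removes alkyl groups from guanine, fell by 0.76 at 6 h (SE 0.19, adjusted p = 0.00221) and rose by 1.06 ± 0.19 at 24 h (adjusted p = 5.06e-05). Parp1, which senses DNA breaks, fell by 0.47 at 6 h (SE 0.13). Among 24 cell cycle genes, Pcna, the sliding clamp of DNA polymerase, rose by 0.73 ± 0.19 at 3 h and 0.92 ± 0.19 at 6 h (list adjusted p = 0.882 and 0.81 with an estimated correlation).

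Among 29 extracellular matrix genes, Timp1, an inhibitor of matrix proteases, rose by 1.00 ± 0.17 at 24 h, Mmp2 rose by 0.77 ± 0.13 (other probe set 0.05), and the elastin gene Eln fell by 0.81 (SE 0.21), among 2 that rose and 5 that fell, with a list adjusted p of 0.805 with an estimated correlation. Among 18 endothelial markers, Kdr, a receptor of vascular endothelial growth factor, fell by 0.82 at 6 h (SE 0.17) and by 0.69 at 24 h (SE 0.17), with list adjusted p values of 0.593 and 0.254 with an estimated correlation. Among apoptosis regulators, the death-promoting Bcl2l11 rose by 1.02 ± 0.17 at 6 h (other probe set -0.44) and the protective Bcl2l1 by 1.28 ± 0.31 at 24 h (list adjusted p = 0.703 and 0.872 with an estimated correlation).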
